A study of Arabidopsis thaliana with 12 samples.

How the data were processed

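The series holds RNA sequencing of 12-day-old Arabidopsis seedlings of Col-0, smeb-1 and smeb-2, untreated or treated with 200 mM NaCl for 6 h, with 2 libraries in each of 6 groups. Reads were trimmed with Trimmomatic 0.32 and aligned with TopHat2 2.0.13 to TAIR10, as named in the submitters' processing notes. The expression table gives FPKM per gene and library as deposited by the authors, that is, fragments scaled by transcript length and by library total. The tool that made this table, the annotation and the library totals are not given in the sources used here. FPKM depends on that scaling, so a change in a few abundant genes shifts all others, and near-identical genes share reads in ways that the table does not record. Strand use is likewise not given, so antisense partners cannot be told apart.

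The splicing tables give, per the file headers, read counts that skip an event and read counts of the other form, joined in a cell, with the authors' p-value and FDR for each event; replicates are pooled in them. Percent values were computed here from these counts with 95% Wilson intervals, which cover counting error only. The enrichment tables give the authors' p-value and adjusted p-value for each term, per the file headers. Before the tables were seen, the authors' lists had been taken for lists of salt-responsive genes, but they hold splicing events, so events were described by type and position, with Fisher's exact test for shares of types, and gene expression was tested for the listed genes.

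The reference annotation is TAIR10.1, whose chromosome coordinates were used for the TAIR10 positions; 32817 of the 33559 gene identifiers matched it, and symbols and products came from it. 0 columns of other series were in the table and 0 columns were identical. Genes with FPKM of at least 1 in at least 2 of the 12 libraries, 20251 in number, were tested on log2(FPKM + 1) with limma 3.58.1 (trend option) in R 4.3.3. The fit had 1 mean for each of the 6 groups and 6 residual degrees of freedom, so every comparison shares an estimate of the spread from all libraries. p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Comparisons were salt against control in each genotype, the mean of both smeb alleles and each allele against Col-0 in control and in salt, the differences in salt response, and the alleles against each other. Differences are on the log2(FPKM + 1) scale, which understates changes of low genes, and ± gives the SE of the fit for differences and the SD of 2 libraries for FPKM. An exact 0 can be a failed estimate, since 11 genes with a median FPKM of at least 5 are listed at 0 in a library. Genes with a group at 0 among those compared are therefore given as FPKM with the adjusted p of the fit. Where their fitted differences are printed, they are marked as dependent on the pseudocount. The relative depth of the libraries, between 0.815 and 1.74, was estimated from the mode of log2 ratios of genes with a mean FPKM under 0.3 in 66 pairs of libraries.

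Gene lists, 22 with 309 genes (10 of them not tested for low values), covered salt and abscisic acid responses, splicing factors, organ markers, clock, defence, flowering and related themes, and were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists, with camera at an estimated correlation and with fry as alternatives. The genes named were set by rule: SmEb, SmEa and RCD1 in every comparison, the 6 largest rises and 6 largest falls, and up to 3 called members of each list with the smallest p. The largest changes were taken among called genes with a mean FPKM of at least 5 whose libraries do not overlap, which was not asked for the salt response. In smeb comparisons and for the salt response both alleles also had to differ from Col-0 in the same direction. Agreement of the alleles in these largest changes is thus built in. Of lists that passed camera up to 3 members are named, and of other lists 1, with values only for a member that was not called. The fitting steps were tested on simulated data with 200 changed genes among 20251. For salt in Col-0 they recovered 93% of genes changed 2-fold and 99% of those changed 4-fold, with 5.88% of calls false. For smeb against Col-0 in control the shares were 97%, 99% and 3.92%, and for the difference in salt response 86%, 99% and 6.09%, with 0 calls of the wrong sign in each. The simulated libraries all had the same spread for a gene, as the fit assumes. In the data the Col-0 salt pair varied more, so these shares need not hold for comparisons that use it.

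Alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, the column suffix as a block, a minimum fold of 2, and each library left out in turn, where the lone library is assumed to vary like the other groups. These and the comparisons were chosen with the lists, except the runs of the gene lists without each Col-0 library, which were added afterwards. With 2 libraries per group, regroupings of samples were not made. Figures were drawn with matplotlib 3.10.9 and tests on counts used scipy 1.17.1 in Python 3.11.15.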

Results

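RNA sequencing of whole Arabidopsis thaliana seedlings, 12 days old, compared the Col-0 wild type with smeb-1 and smeb-2, a pair of mutant lines of SmEb. SmEb encodes an Sm protein, one of the ring-forming proteins at the core of the spliceosomal small nuclear ribonucleoproteins. Seedlings of each line were either left without salt or treated with 200 mM NaCl for 6 h, giving 6 groups of 2 libraries and 12 libraries in all. Expression was deposited as FPKM for 33559 genes, and 20251 genes that reached an FPKM of 1 in at least 2 libraries were tested. The libraries are told apart below by the 0 or 1 that ends their column names, and replicate numbers in the labels could not be tied to these. Nothing says whether the libraries of a group came from separately grown seedlings, so the p-values measure only the spread between these samples. Read totals are not given, and FPKM summed to between 738721 and 776714 in the salt-treated libraries and to between 827553 and 848257 in the controls. Relative depth, estimated from the steps of low values, ranged from 0.815 in smeb-1 salt suffix 1 to 1.74 in smeb-2 control suffix 0. The 10 most abundant genes held between 7.85% and 8.59% of FPKM in controls and between 4.05% and 5.68% in salt. Libraries of one group correlated across genes at r between 0.984 and 0.994, the lowest being the Col-0 salt pair, whose median absolute log2 difference was 0.167 against 0.0847 to 0.0998 in the other groups. The fit shares its estimate of the spread over all 6 groups. SEs and p-values thus tend to be too small in comparisons that use Col-0 salt and too large in the others. Across genes, the first principal component held 76.1% of the variance and separated salt from control, and the second (9.72%) separated Col-0 from both smeb lines. One label field of the treated samples names Cd while their titles and treatment fields name salt, and they are described here as salt-treated. For the controls one field gives an untreated period of 6 h while the protocol allows 0 or 6 h, so their harvest time is uncertain.

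SmEb itself (AT2G18740, TAIR10, chromosome 2, 8123195 to 8125078, plus strand) was measured first, since its level checks the labels. Its FPKM was 58.9 and 55.1 in the Col-0 control libraries and 73.3 and 76.1 in Col-0 salt. It was 27.6 and 26.0 in smeb-1 control, 23.2 and 22.9 in smeb-1 salt, 4.93 and 6.24 in smeb-2 control, and 1.92 and 2.04 in smeb-2 salt, so every mutant library lay below every Col-0 library. The mean of both smeb lines was lower than Col-0 by 2.1 ± 0.0796 (log2 difference ± SE, adjusted p = 9e-07) in control and by 3.16 ± 0.0796 (adjusted p = 8.78e-08) in salt. Salt raised SmEb in Col-0 by 0.39 ± 0.0919 (adjusted p = 0.00455), and its salt response was lower in the smeb lines by 1.06 ± 0.113 (adjusted p = 5.98e-04). With salt SmEb fell by 1.14 ± 0.0919 in smeb-2 (adjusted p = 4.21e-06) and was at −0.21 ± 0.0919 in smeb-1 (adjusted p = 0.0733, but 0.0345 under median-of-ratios scaling, 0.0234 under quantile normalization, and 0.0273 and 0.0276 without either smeb-2 control library). The paralog SmEa (AT4G30330, chromosome 4, 14836548 to 14838149, minus strand) had FPKM means between 25.3 and 32.7 in the 6 groups. It differed between smeb and Col-0 by 0.08 ± 0.0811 in control (adjusted p = 0.525) and 0.11 ± 0.0811 in salt (adjusted p = 0.328). Reads shared by these near copies could have been split between them in the deposited values.

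The labels name RCD1 (AT1G32230, chromosome 1, 11611891 to 11617419, plus strand), a regulator of oxidative and salt stress responses, as the transcript whose splicing the study followed. Its total FPKM was 100 and 103 in Col-0 control, 97.8 and 130 in Col-0 salt, and 112 and 117 in smeb-1 control. It was 94.3 and 85.9 in smeb-1 salt, 118 and 118 in smeb-2 control, and 92.7 and 97.5 in smeb-2 salt. RCD1 did not pass in 4 comparisons, at 0.15 ± 0.110 for salt in Col-0 (adjusted p = 0.272) and 0.19 ± 0.0952 for smeb against Col-0 in control (adjusted p = 0.182). It was at −0.28 ± 0.0952 in salt (adjusted p = 0.0520) and −0.47 ± 0.135 for the difference in salt response (adjusted p = 0.0554). Salt lowered RCD1 in smeb-1 by 0.34 ± 0.110 (adjusted p = 0.0224) and in smeb-2 by 0.31 ± 0.110 (adjusted p = 0.0332). These calls were lost without single libraries of the same line (adjusted p between 0.0555 and 0.129 in smeb-1 and between 0.0720 and 0.138 in smeb-2), and in smeb-2 with no filter (0.0523). In the 4 other comparisons the RCD1 calls changed when Col-0 salt suffix 0 was left out, which leaves only suffix 1, at 130 FPKM, in that group. RCD1 was then at 0.35 for salt in Col-0, −0.48 for smeb against Col-0 in salt and −0.67 for the salt response. Without either Col-0 salt library RCD1 stayed at 0.19 in control. That comparison does not use these libraries, so only the estimated spread changed there. Quantile normalization also brought RCD1 past the threshold in salt (adjusted p = 0.0362) and for the salt response (adjusted p = 0.0465). Gene-level FPKM does not separate RCD1 isoforms.

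**Figure D1:**
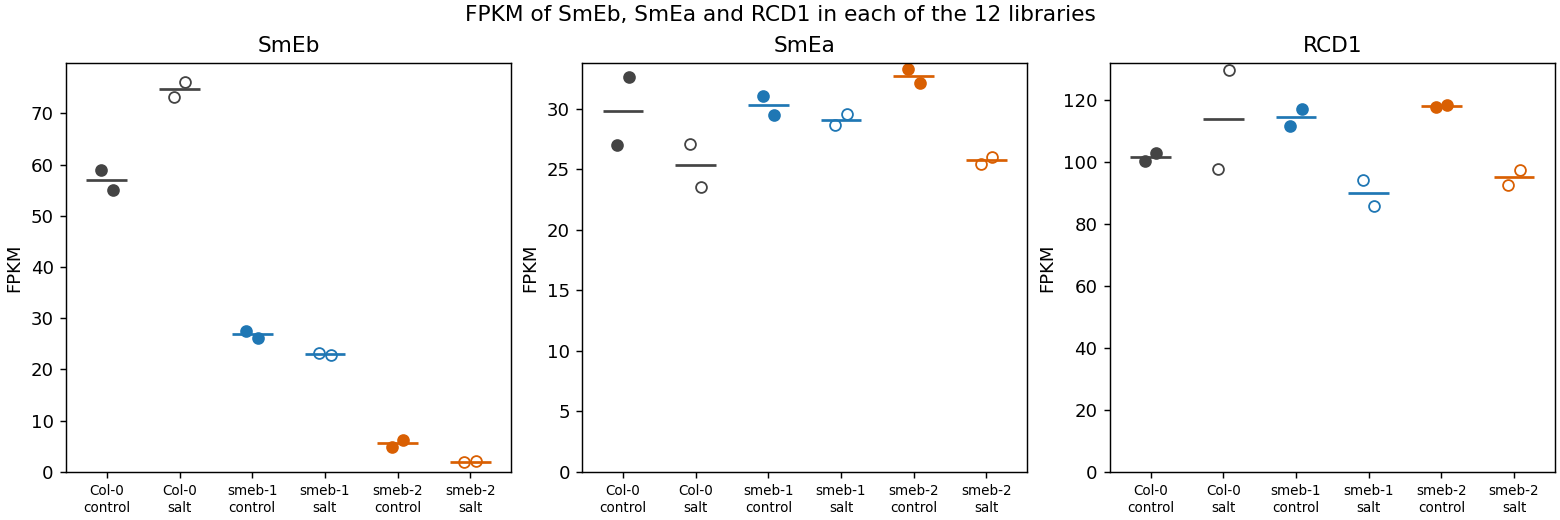
FPKM (vertical axis, from 0) of SmEb, SmEa and RCD1 in the 12 libraries; each point is a library, each line a group mean (n = 2), with filled points for control and open points for salt. SmEb group means were 57.0 and 74.7 in Col-0, 26.8 and 23.0 in smeb-1 and 5.58 and 1.98 in smeb-2, and SmEa means lay between 25.3 and 32.7.

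The first comparison asked how 6 h of salt changed expression in the wild type. Since the harvest time of the controls is uncertain, a difference in time of day cannot be told apart from salt in comparisons of salt against control. In Col-0, genes of the abscisic acid and osmotic stress response rose steeply and those of the light-harvesting complexes fell steeply. With an estimated correlation neither the abscisic acid and osmotic (adjusted p = 0.204) nor the photosynthesis list (0.0994) passed camera. KIN1, a cold- and abscisic acid-induced gene, went from 70.4 ± 2.52 to 1728 ± 149 FPKM (mean ± SD, n = 2 here and below). RD29A, a classic osmotic stress marker, rose from 124 ± 18.1 to 1151 ± 102, and RD26, a NAC transcription factor, from 10.8 ± 0.862 to 129 ± 5.81. LHCB3, a chlorophyll-binding antenna protein of photosystem II, fell from 4811 ± 154 to 35.5 ± 2.64 FPKM, and LHCB2.1 from 1907 ± 40.3 to 16.4 ± 2.1. The largest rises were those of the bHLH factor gene AT1G10585 (5.73 ± 0.425, log2 difference ± SE), the ERF factor RAP2.6 (5.42 ± 0.289) and the glyoxalase family gene GLYI7 (5.42 ± 0.351). They were followed by the oxygenase gene AT2G38240 (5.15 ± 0.277), the glycosyltransferase UGT74E2 (5.11 ± 0.404) and the uncharacterised AT5G24640 (4.96 ± 0.109), with adjusted p of 3.4e-06 or lower. The largest falls were all of light-harvesting genes: LHCB1.1 (−7.65 ± 0.284), LHCB2.2 (−7.52 ± 0.132), LHCB1.2 (−7.11 ± 0.154), LHCB2.3 (−7.10 ± 0.146), LHCB3 (−7.04 ± 0.0796) and LHCB2.1 (−6.78 ± 0.0932), with adjusted p of 3.15e-08 or lower. Members of the LHCB1 and LHCB2 families are nearly identical, so values of single members are uncertain.

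Of the 22 gene lists written before the data were examined, 11 passed camera in Col-0. For these 22 lists, counts adjusted over the list alone equalled those over all genes unless both are given. Among abscisic acid and osmotic markers, 16 of 17 measured members rose, 0 fell and 1 did not pass, or 17 and 0 adjusted over the list alone (median log2 difference 2.21, adjusted p = 5.02e-07 by camera, and adjusted p = 0.204 with an estimated correlation). Of the PP2C phosphatases that restrain abscisic acid signalling, 8 of 8 rose, 0 fell and 0 did not pass (adjusted p = 7.58e-05 by camera, and adjusted p = 0.204 with an estimated correlation). ABI1 was at 2.30 ± 0.0941, HAB1 at 2.25 ± 0.0949 and HAI3 at 4.02 ± 0.215. For abscisic acid synthesis and breakdown, 6 of 9 measured members rose, 1 fell and 2 did not pass (adjusted p = 0.0372 by camera, and adjusted p = 0.204 with an estimated correlation). Those that rose included the catabolic hydroxylases CYP707A1 (1.96 ± 0.115), CYP707A2 (1.66 ± 0.116) and CYP707A4 (1.56 ± 0.137). In the CBF and DREB list, 6 of 6 measured members rose, 0 fell and 0 did not pass (adjusted p = 0.00641 by camera, and adjusted p = 0.268 with an estimated correlation). CBF1 was at 2.46 ± 0.135, DREB2A at 2.2 ± 0.182 and CBF3 at 1.45 ± 0.159. For targets of mitochondrial retrograde signalling, 12 of 15 measured members rose, 1 fell and 2 did not pass (adjusted p = 1.48e-04 by camera, and adjusted p = 0.264 with an estimated correlation). Among them were NAC013 (2.54 ± 0.106), OM66 (2.65 ± 0.123) and the zinc finger gene ZAT10 (2.37 ± 0.120). Among jasmonate genes, 13 of 18 measured members rose, 3 fell and 2 did not pass, or 14 and 3 adjusted over the list alone (adjusted p = 0.0324 by camera, and adjusted p = 0.341 with an estimated correlation). The regulators MYC2 and JAZ1 were at 0.92 ± 0.0724 and 1.70 ± 0.135 and the lipoxygenase LOX2 at 2.38 ± 0.219. Of the senescence genes, 5 of 6 rose, 0 fell and 1 did not pass (adjusted p = 0.0338 by camera, and adjusted p = 0.268 with an estimated correlation). SAG29 was at 3.34 ± 0.237 and the NAC factors ORE1 at 2.60 ± 0.266 and NAP at 3.32 ± 0.405.

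The photosynthesis list went the other way: 2 of 22 measured members rose, 18 fell and 2 did not pass (median −3.26, adjusted p = 1.35e-11 by camera, and adjusted p = 0.0994 with an estimated correlation), LHCB4.2 being at −5.19 ± 0.0808. Of the cell cycle genes, 0 of 11 rose, 10 fell and 1 did not pass (adjusted p = 1.84e-04 by camera, and adjusted p = 0.264 with an estimated correlation). Those that fell included the cytokinesis syntaxin KN (−1.17 ± 0.0702) and the mitotic kinases CDKB2;2 (−1.06 ± 0.0879) and CDKB2;1 (−1.34 ± 0.115). Among circadian clock genes, 4 of 15 measured members rose, 9 fell and 2 did not pass (adjusted p = 0.0145 by camera, and adjusted p = 0.204 with an estimated correlation). LNK2 was at −3.28 ± 0.0916, GI at −3.43 ± 0.101 and PRR7 at −4.36 ± 0.180. For flowering time genes, 0 of 9 measured members rose, 4 fell and 5 did not pass (adjusted p = 0.0453 by camera, and adjusted p = 0.204 with an estimated correlation). They were the repressors SVP (−0.94 ± 0.0642), FLM (−0.71 ± 0.0950) and MAF2 (−0.53 ± 0.0995) with 1 other. The flowering call was lost under median-of-ratios scaling (adjusted p = 0.0511) and without Col-0 control suffix 1 (0.0644), Col-0 salt suffix 0 (0.0613) or Col-0 salt suffix 1 (0.0849).

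The other 11 lists did not pass camera, and their members went both ways in most. For abscisic acid receptors, 1 of 9 measured members rose, 5 fell and 3 did not pass (adjusted p = 0.0756, and 0.0346 without Col-0 salt suffix 1), PYL4 falling by 3.05 ± 0.166. Of the ion transport genes, 9 of 18 rose, 5 fell and 4 did not pass (adjusted p = 0.405), the vacuolar sodium/proton exchanger NHX1 rising by 1.55 ± 0.0783. For compatible solutes, 6 of 11 measured members rose, 1 fell and 4 did not pass, or 6 and 2 adjusted over the list alone (adjusted p = 0.0898), the proline synthesis gene P5CS2 rising by 1.99 ± 0.0901. Among genes that scavenge reactive oxygen, 8 of 23 measured members rose, 5 fell and 10 did not pass (adjusted p = 0.435), the glutathione reductase GR1 rising by 2.56 ± 0.0951. In the family of RCD1 and its SRO relatives, 3 of 6 measured members rose, 0 fell and 3 did not pass (adjusted p = 0.185), SRO5 rising by 2.36 ± 0.185. For metal and sulfur genes, included because a label names Cd, 7 of 14 measured members rose, 4 fell and 3 did not pass (adjusted p = 0.343), the sulfate assimilation gene APR2 rising by 2.80 ± 0.0666. Among heat shock genes, 5 of 12 measured members rose, 5 fell and 2 did not pass (adjusted p = 0.579), with a median of −0.01 and a mean of 0.23, and HSP90.1 falling by 2.25 ± 0.116. Of the salicylate genes, 4 of 12 rose, 5 fell and 3 did not pass (adjusted p = 0.541), the immune regulator EDS1 falling by 0.93 ± 0.0903. For root markers, 3 of 14 measured members rose, 5 fell and 6 did not pass (adjusted p = 0.343), the nitrate transporter NRT2.1 rising by 3.19 ± 0.240. Of the Sm and LSm proteins, 10 of 24 rose, 3 fell and 11 did not pass, or 9 and 3 adjusted over the list alone (adjusted p = 0.603), LSM7 falling by 0.61 ± 0.0541. For SR splicing factors, 6 of 20 measured members rose, 7 fell and 7 did not pass (adjusted p = 0.343), SR34B falling by 1.67 ± 0.0923. The named genes of these lists had adjusted p of 1.4e-05 or lower.

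In all, 12520 genes changed with salt in Col-0, 6913 higher and 5607 lower (55.2% higher, but 49.0% under quantile normalization), of which 3159 changed at least 2-fold on the log2(FPKM + 1) scale, which understates changes of low genes. In smeb-1, 11708 genes changed (6273 higher, 5435 lower, or 53.6% higher, but 47.1% under quantile normalization), and in smeb-2, 12085 (6482 higher, 5603 lower, or 53.6% and 45.4%). The abscisic acid and osmotic list rose in both mutants, with 15 higher and 0 lower of 17 in smeb-1 and 17 higher and 0 lower of 17 in smeb-2 (adjusted p = 5.85e-07 and 4.44e-09 by camera, but 0.152 and 0.146 with an estimated correlation). The photosynthesis list had 3 higher and 17 lower of 22 in smeb-1 and the same counts in smeb-2. Col-0 and smeb-1 shared 5219 genes called higher and 4186 called lower, where independent lists would share 2141 and 1505, and 126 were called in opposite directions. Col-0 and smeb-2 shared 5431 and 4341 (2213 and 1551 for independent lists, 103 opposite), and smeb-1 and smeb-2 shared 5480 and 4594 (2008 and 1504, 8 opposite). SmEa was at −0.23 ± 0.0937 in Col-0 and did not pass (adjusted p = 0.0585). It passed under median-of-ratios scaling (0.0337), quantile normalization (0.0140), and without Col-0 control suffix 0 (0.0120) or Col-0 salt suffix 0 (0.0167). It was at −0.06 ± 0.0937 in smeb-1 (adjusted p = 0.630) and −0.33 ± 0.0937 in smeb-2 (adjusted p = 0.0114, but 0.0629 without smeb-2 control suffix 0 and 0.0559 without smeb-2 salt suffix 0). With an estimated correlation 0 of the 22 lists passed camera in Col-0, and by fry, which tests each list for movement one way without comparing it with other genes, 20 passed.

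**Figure D2:**
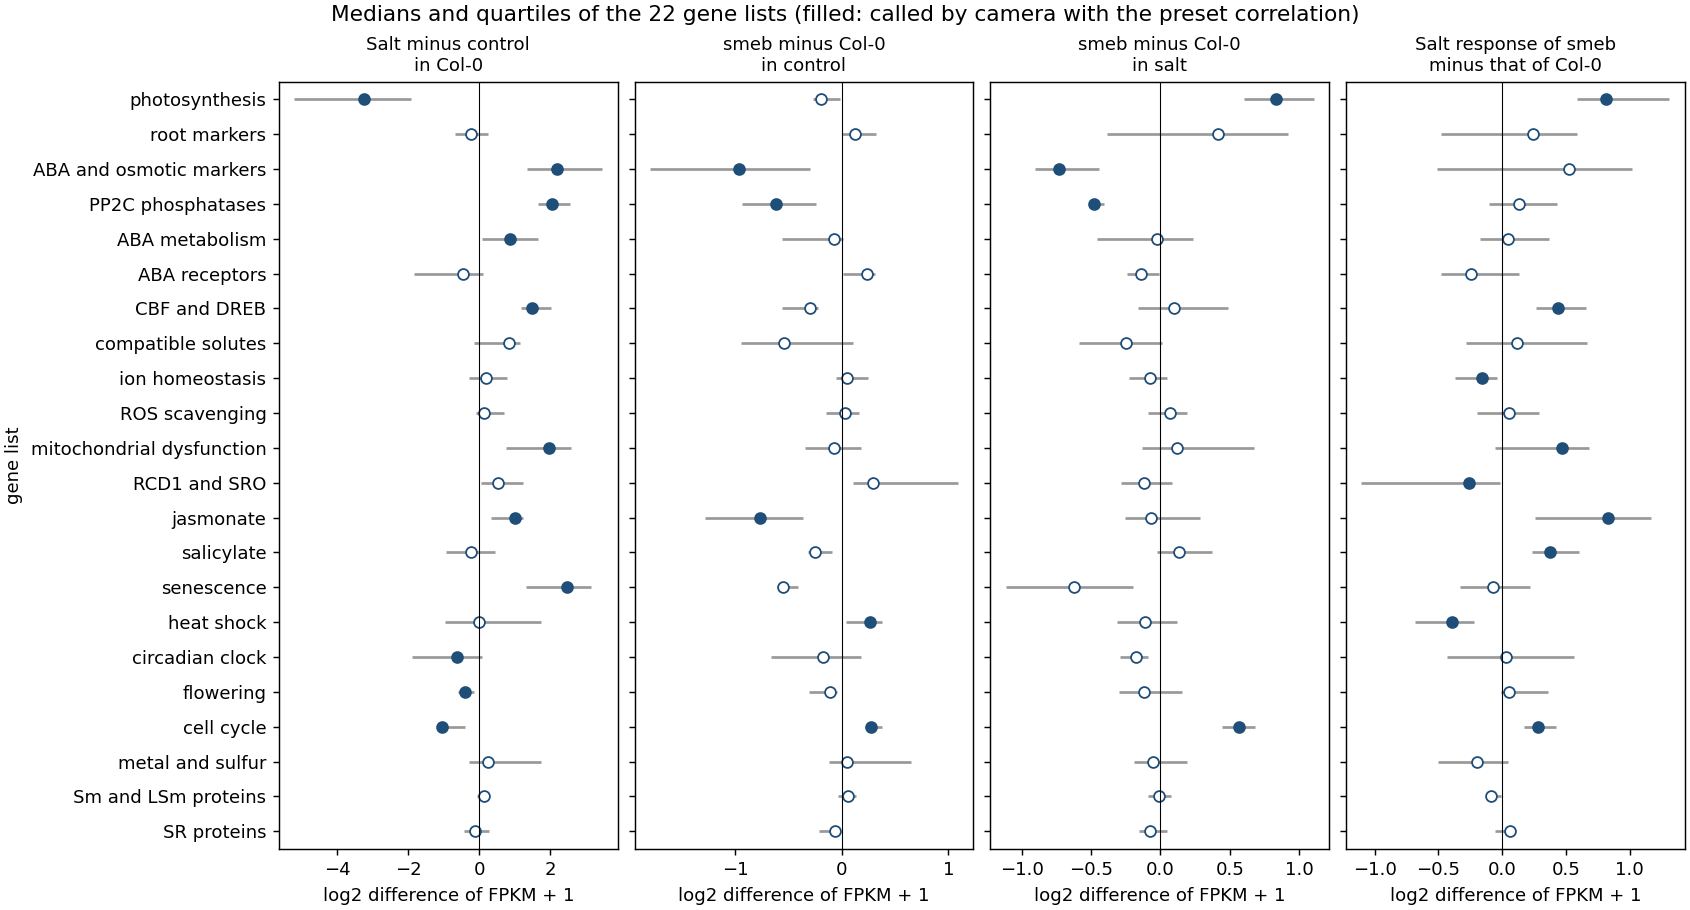
Median log2 difference (horizontal axis, lines from the lower to the upper quartile of members) of the 22 gene lists in 4 comparisons; filled points passed camera with a preset correlation of 0.01. Photosynthesis genes had medians of −3.26 with salt in Col-0 and 0.83 for salt-treated smeb against salt-treated Col-0.

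The next comparison asked how the smeb lines differed from Col-0 without salt, using the mean of both lines. Untreated smeb seedlings had less transcript of abscisic acid, osmotic stress and jasmonate genes. With an estimated correlation the abscisic acid and osmotic (adjusted p = 0.336) and jasmonate (0.235) lists did not pass camera. The phosphatase gene PEPC1 was at 79.5 ± 0.215 FPKM in Col-0, 3.40 ± 1.38 in smeb-1 and 2.74 ± 0.126 in smeb-2, a log2 difference of −4.33 ± 0.148. The pyrophosphatase gene PS2 (−3.64 ± 0.118), the phosphate-sensing gene SPX3 (−3.62 ± 0.107) and the acid phosphatase PAP14 (−3.61 ± 0.220) are known for induction by phosphate starvation. So are the galactolipid synthase MGDC (−3.28 ± 0.143) and the noncoding IPS1 (−3.27 ± 0.370), which completed the 6 largest falls (adjusted p of 2.64e-04 or lower). The largest rises were those of the pyruvate decarboxylase gene AT4G33070 (3.56 ± 0.218), the salicylate marker PR1 (3.24 ± 0.363) and AT2G17850 of the rhodanese family (3.10 ± 0.268). They were followed by the unnamed gene AT4G04223 (2.83 ± 0.0844), the crossover factor HEI10 (2.80 ± 0.122) and the thioredoxin TH8 (2.69 ± 0.198), with adjusted p of 2.53e-04 or lower. AT4G33070 went from 2.96 ± 0.172 FPKM in Col-0 to 52.1 ± 6.36 in smeb-1 and 41.8 ± 17.7 in smeb-2, and PR1 from 59.5 ± 16.5 to 790.3 ± 31.4 and 442 ± 271.

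Among jasmonate genes, 0 of 18 measured members were higher, 14 were lower and 4 did not pass (median −0.77, adjusted p = 1.6e-08 by camera, and adjusted p = 0.235 with an estimated correlation). The lower genes included the biosynthesis genes OPR3 (−1.37 ± 0.0781) and AOC1 (−1.53 ± 0.122) and the regulator MYC2 (−0.69 ± 0.0627). For abscisic acid and osmotic markers, 1 of 17 measured members were higher, 11 were lower and 5 did not pass, or 1 and 12 adjusted over the list alone (median −0.97, adjusted p = 1.13e-06 by camera, and adjusted p = 0.336 with an estimated correlation). RD29A was at 124 ± 18.1 FPKM in Col-0, 22.3 ± 2.43 in smeb-1 and 16.9 ± 1.04 in smeb-2. RD20, a caleosin, was lower by 2.97 ± 0.164 and RD22 by 1.28 ± 0.0924. Over this list the median absolute log2 difference between replicate libraries was 0.130 in Col-0 control, the lowest of the 6 groups, 0.184 in smeb-1 control and 0.143 in smeb-2 control. Single genes of this response, picked after their values were seen, differed more between the Col-0 control libraries. AT3G02480 was at 51.1 FPKM in suffix 0 and 2.99 in suffix 1, LTP4 at 71.6 and 7.41, and LEA7 at 31.1 and 3.59. For the PP2C phosphatases, 0 of 8 measured members were higher, 6 were lower and 2 did not pass (adjusted p = 1.69e-04 by camera, and adjusted p = 0.336 with an estimated correlation). HAB1 was at −0.87 ± 0.0822, HAI1 at −2.05 ± 0.212 and ABI1 at −0.65 ± 0.0815. Of the cell cycle genes, 4 of 11 were higher, 0 were lower and 7 did not pass, or 5 and 0 adjusted over the list alone (adjusted p = 0.0103 by camera, and adjusted p = 0.415 with an estimated correlation). The replication genes MCM5 and PCNA1 were at 0.54 ± 0.0964 and 0.51 ± 0.0996 and KN at 0.29 ± 0.0608. Among heat shock genes, 5 of 12 measured members were higher, 0 were lower and 7 did not pass (adjusted p = 0.0391 by camera, and adjusted p = 0.415 with an estimated correlation). HSP23.6 was at 0.73 ± 0.134, HSP90.1 at 0.39 ± 0.1 and HSP70 at 0.32 ± 0.0807. The named genes of these 5 lists had adjusted p of 0.0183 or lower.

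The other 17 lists did not pass, and each held members that differed. Photosynthesis genes split into 3 higher and 7 lower of 22 (4 and 8 adjusted over the list alone), LHCB2.1 being lower by 0.82 ± 0.0807. Clock genes split into 4 higher and 6 lower of 15 (4 and 7 adjusted over the list alone), LNK2 being lower by 1.23 ± 0.0793. Ion transport genes had 6 higher and 1 lower of 18, with the plasma membrane proton pump AHA2 at 0.68 ± 0.0826. Compatible solute genes had 2 higher and 6 lower of 11 (3 and 6 adjusted over the list alone), with the galactinol synthase GOLS2 at −2.63 ± 0.135. The floral repressor FLC (−1.92 ± 0.121) was 1 of 3 lower flowering genes, at 3.06 ± 0.201 FPKM in Col-0 and 0.0598 ± 0.0845 and 0.0827 ± 0.0270 in the mutants. The salicylate list had 1 higher and 3 lower of 12 (1 and 4 adjusted over the list alone) and the Sm and LSm list 1 higher and 1 lower of 24, the lower one being SmEb. The SR factors had 1 higher and 3 lower of 20 (0 and 3 adjusted over the list alone), with RS2Z33 at −0.35 ± 0.0699. Single members of the remaining lists included CAT2 (−0.89 ± 0.0661), a catalase, PCS1 (−0.84 ± 0.0669), which makes phytochelatins, and ABA1 (−0.60 ± 0.0888), which makes an abscisic acid precursor. Others were the receptor PYR1 (0.36 ± 0.0756), SRO5 (1.32 ± 0.160), NDB4 (0.85 ± 0.136), the root hair gene LRX1 (0.60 ± 0.149), CBF3 (−0.64 ± 0.138) and the chlorophyll breakdown gene NYE1 (−0.50 ± 0.155). All these named genes passed, with adjusted p of 0.0403 or lower.

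In control, 4969 genes differed between smeb and Col-0, 2345 higher and 2624 lower (47.2% higher, but 52.8% under quantile normalization), of which 489 by at least 2-fold. The count was 2615 without Col-0 control suffix 0 and 2385 without suffix 1, and without one of these the heat shock list (adjusted p = 0.0948 without suffix 0, where flowering passed at 0.0411) and the calls of PYR1, RS2Z33, LRX1, CBF3, HSP90.1, HSP70, NYE1, PCNA1 and KN (adjusted p between 0.0564 and 0.326) were lost. HSP70 also failed under quantile normalization (adjusted p = 0.0695) and without smeb-1 control suffix 1 (0.0514) or smeb-2 control suffix 1 (0.0558), and NYE1 with no filter (0.0726) and without any of the 8 smeb libraries (between 0.0518 and 0.0918).

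In salt, smeb seedlings had more transcript of photosynthesis and cell cycle genes than Col-0 and less of abscisic acid, osmotic and PP2C genes. By camera with an estimated correlation only photosynthesis passed, and the 3 other lists did not (adjusted p = 0.357 for each). These results are for the mean of both lines, and fewer abscisic acid and osmotic markers passed in smeb-2 than in smeb-1, as given below. LHCB3 was at 35.5 ± 2.64 FPKM in salt-treated Col-0, 135 ± 0.409 in smeb-1 and 90.4 ± 7.74 in smeb-2, and RD29A at 1151 ± 102, 485 ± 56.0 and 624 ± 65.7. PR1 showed the largest rise among genes detected in every library (4.03 ± 0.363), followed by the unnamed genes AT4G04223 (2.71 ± 0.0844) and AT1G67105 (2.70 ± 0.277) and the MATE efflux gene AT2G04070 (2.42 ± 0.125). The largest falls besides SmEb were those of the defensin PDF1.2A (−2.46 ± 0.415), the phosphate starvation gene AT5G03545 (−2.26 ± 0.361), the methyltransferase HOL2 (−2.2 ± 0.140) and the transcription factor MYB121 (−2.19 ± 0.130). All of these genes had adjusted p of 0.00298 or lower. Other genes among the largest changes had libraries listed at 0, so their FPKM is given instead of a fold. The U1 small nuclear RNA gene U1.5 was at 0 and 0 in Col-0 salt, 25.7 and 27.1 in smeb-1 salt and 9.80 and 9.61 in smeb-2 salt (adjusted p = 0.00119). AT4G30097 was at 22.6 and 36.8 in Col-0 salt and 0 in all 4 salt-treated smeb libraries (adjusted p = 0.00507). The chloroplast gene ATCG00140 was at 0 and 1.79 in Col-0 salt and between 4.83 and 12.0 in the smeb libraries (adjusted p = 0.0253, 0.0519 with no filter and up to 0.126 when Col-0 salt suffix 0 was left out).

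Among photosynthesis genes, 21 of 22 measured members were higher, 0 were lower and 1 did not pass (median 0.83, adjusted p = 7.43e-20 by camera, and adjusted p = 0.0255 with an estimated correlation). LHCB3 was at 1.61 ± 0.0689, LHCB2.1 at 1.61 ± 0.0807 and LHCB4.2 at 1.36 ± 0.0700. For root markers, which did not pass camera, 8 of 14 measured members were higher, 2 were lower and 4 did not pass, or 8 and 4 adjusted over the list alone (median 0.42, mean 0.22, adjusted p = 0.168). CASP2, which builds the Casparian strip, was lower by 1.26 ± 0.109. Of the cell cycle genes, 9 of 11 were higher, 0 were lower and 2 did not pass, or 10 and 0 adjusted over the list alone (adjusted p = 2.68e-07 by camera, and adjusted p = 0.357 with an estimated correlation). KN was at 0.57 ± 0.0608, PCNA1 at 0.73 ± 0.0996 and the mitotic cyclin CYCB1;2 at 0.76 ± 0.112. For abscisic acid and osmotic markers, 0 of 17 measured members were higher, 12 were lower and 5 did not pass, or 0 and 13 adjusted over the list alone (median −0.73, adjusted p = 3.52e-06 by camera, and adjusted p = 0.357 with an estimated correlation). RD29A was at −1.07 ± 0.112, RD26 at −0.91 ± 0.129 and the dehydrin ERD10 at −0.66 ± 0.103. The median absolute log2 difference between replicate libraries over this list was 0.270 in Col-0 salt, 0.236 in smeb-1 salt and 0.215 in smeb-2 salt. For the PP2C phosphatases, 0 of 8 measured members were higher, 6 were lower and 2 did not pass, or 0 and 7 adjusted over the list alone (adjusted p = 0.00113 by camera, and adjusted p = 0.357 with an estimated correlation). ABI1 was at −0.51 ± 0.0815, HAB1 at −0.51 ± 0.0822 and HAB2 at −0.33 ± 0.0586.

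Members of other lists that differed in salt included the abscisic acid hydroxylase CYP707A3 (0.78 ± 0.0871), the receptor PYL1 (0.37 ± 0.0712), the vacuolar calcium exchanger CAX1 (−0.75 ± 0.105), P5CS2 (−0.43 ± 0.0780) and the ascorbate peroxidase APX2 (1.07 ± 0.125). Others were the RCD1 relative SRO1 (−0.29 ± 0.0670), the alternative NADH dehydrogenase NDB4 (1.90 ± 0.136), the SR factor RS41 (−0.38 ± 0.0779), CBF1 (0.59 ± 0.117) and the clock gene CCA1 (−0.47 ± 0.111). FLC (−1.49 ± 0.121), HSP18.2 (1.41 ± 0.154), ORE1 (−0.90 ± 0.230) and the metal pump HMA4 (−0.36 ± 0.0842) differed as well, all of these genes with adjusted p of 0.0187 or lower. PDF1.2A, a target of jasmonate and ethylene, was at 1.43 ± 1.29 FPKM in smeb-1 salt, 4.1 ± 0.200 in smeb-2 salt and 20.6 ± 15.2 in Col-0 salt. The jasmonate list had 4 higher and 2 lower of 18 (adjusted p = 0.842). The mitochondrial retrograde list had 6 higher and 1 lower of 15 (7 and 2 adjusted over the list alone, adjusted p = 0.115, and 0.000297 without Col-0 salt suffix 1).

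In salt, 5617 genes differed between smeb and Col-0, 2592 higher and 3025 lower, of which 327 by at least 2-fold. Of the 5617, 1941 genes were called in the same direction as in control and 217 in the opposite one. The 46.1% higher became 50.9% under median-of-ratios scaling, 53.0% under quantile normalization, 55% without Col-0 salt suffix 1, 50.7% without smeb-2 salt suffix 0 and 58.2% when only these groups were fitted. The count was 2091 when only these groups were fitted, and 2982 without Col-0 salt suffix 1, where SRO1 (adjusted p = 0.0934), RS41 (0.0528), ORE1 (0.134) and HMA4 (0.0729) were lost, while the PP2C list failed without Col-0 salt suffix 0 (0.137), ORE1 also without smeb-2 salt suffix 0 (0.0550), and CBF1 with a pseudocount of 0.1 (0.0997).

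The interaction asked whether the salt response itself differed between smeb and Col-0, which bears on the study's question of a role for SmEb in salt responses. Photosynthesis genes fell less in the smeb lines, and jasmonate genes had a more positive salt response there, although with an estimated correlation the jasmonate list did not pass camera (adjusted p = 0.172). The jasmonate list was lower in untreated smeb and did not pass camera between smeb and Col-0 in salt. Its difference in response thus went with the control difference, for which genotype and batch cannot be told apart here. LHCB2.1 went from 1051 ± 84.7 to 60.7 ± 0.403 FPKM in smeb-1 and from 1112 ± 95.1 to 44.5 ± 1.58 in smeb-2. In Col-0 it went from 1907 ± 40.3 to 16.4 ± 2.1, a difference in response of 2.43 ± 0.114 (log2 ± SE). The jasmonate biosynthesis gene AOC1 went from 82.1 ± 0.630 to 43.2 ± 7.29 in Col-0 but from 26.0 ± 3.01 to 65.8 ± 0.611 in smeb-1 and from 30.0 ± 6.22 to 66.4 ± 0.387 in smeb-2. Other large positive differences were those of PS2 (3.58 ± 0.167), PEPC1 (3.34 ± 0.210), the phospholipase NPC4 (2.68 ± 0.165) and RD20 (2.77 ± 0.232). Large negative ones were those of AT4G39675 (−3.90 ± 0.245), the alcohol dehydrogenase ADH1 (−3.60 ± 0.303), TH8 (−3.03 ± 0.280), AT2G17850 (−2.98 ± 0.379) and AT4G33070 (−2.80 ± 0.309), all with adjusted p of 0.00146 or lower. PS2 was at 114 ± 3.74 FPKM in Col-0 control and between 6.97 and 8.72 in the other groups' means. ADH1 went from 11.0 ± 0.959 to 113 ± 18 in Col-0, from 80.1 ± 13.4 to 47.1 ± 5.89 in smeb-1 and from 66.0 ± 28.8 to 64.7 ± 4.2 in smeb-2. U1.5 (adjusted p = 0.0107) was at 98.4 and 32.6 FPKM in Col-0 control, 85.4 and 55.4 in smeb-1 control and 85.9 and 16.2 in smeb-2 control. AT4G30097 (adjusted p = 0.0187) was at 0 in the control libraries except smeb-1 suffix 0, at 24.0. The response of SmEa differed by 0.03 ± 0.115 (adjusted p = 0.885).

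In the photosynthesis list, 17 of 22 had a more positive and 0 a more negative response (19 and 0 adjusted over the list alone) in smeb (median 0.82, adjusted p = 7.22e-20 by camera, and adjusted p = 0.0255 with an estimated correlation). Among them were LHCB3 (2.02 ± 0.0975) and LHCB4.2 (1.84 ± 0.0990). Among jasmonate genes, 10 of 18 had a more positive and 0 a more negative response (11 and 0 adjusted over the list alone, median 0.83, adjusted p = 1.99e-07 by camera, and adjusted p = 0.172 with an estimated correlation). Among them were AOC1 (2.15 ± 0.172), MYC2 (1.003 ± 0.0886) and OPR3 (1.23 ± 0.110). Of the mitochondrial retrograde genes, 5 of 15 had a more positive and 0 a more negative response (6 and 0 adjusted over the list alone, adjusted p = 0.0132 by camera, and adjusted p = 0.501 with an estimated correlation). Among them were the alternative oxidase AOX1A (1.01 ± 0.103), AT12CYS (2.33 ± 0.369) and NDB4 (1.05 ± 0.192). In the CBF and DREB list, 2 of 6 had a more positive and 0 a more negative response (adjusted p = 0.0245 by camera, and adjusted p = 0.501 with an estimated correlation). CBF2 was at 1.60 ± 0.318 and CBF1 at 0.73 ± 0.166. In the salicylate list, 2 of 12 had a more positive and 0 a more negative response (adjusted p = 0.0201 by camera, and adjusted p = 0.559 with an estimated correlation). SARD1 was at 0.996 ± 0.188 and EDS1 at 0.47 ± 0.111. By limma, 0 cell cycle genes passed over all genes, although 5 of 11 did adjusted over the list alone, all more positive (adjusted p = 0.00750 by camera, and adjusted p = 0.501 with an estimated correlation). CDKB2;1 was at 0.48 ± 0.140 (adjusted p = 0.0591). Ion transport genes had a negative median of −0.16. Of them, 1 of 18 had a more positive and 4 a more negative response (1 and 5 adjusted over the list alone, adjusted p = 0.0132 by camera, and adjusted p = 0.388 with an estimated correlation). CAX1 was at −1.19 ± 0.149, AHA2 at −0.72 ± 0.117 and NHX1 at −0.43 ± 0.0959. Of the heat shock genes, 1 of 12 had a more positive and 2 a more negative response (2 and 7 adjusted over the list alone, adjusted p = 0.0381 by camera, and adjusted p = 0.545 with an estimated correlation). HSP70 was at −0.72 ± 0.114, HSP90.1 at −0.67 ± 0.142 and HSP18.2 at 1.43 ± 0.217. In the RCD1 family, 0 of 6 had a more positive and 2 a more negative response (0 and 3 adjusted over the list alone, adjusted p = 0.0490 by camera, and adjusted p = 0.501 with an estimated correlation). SRO5 was at −1.66 ± 0.226. SRO4 was listed at 0 in both Col-0 salt libraries, with means of 0.242 FPKM in Col-0 control, 2.79 and 1.87 in the untreated and 0.0447 and 0.0291 in the salt-treated smeb lines (adjusted p = 0.0312).

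In lists that did not pass, members with a different response included P5CS1 (1.51 ± 0.133), the hydroxylase CYP707A2 (0.90 ± 0.142) and the phosphatase HAI1 (1.64 ± 0.3). Others were PYR1 (−0.60 ± 0.107), CAT2 (1.05 ± 0.0935), CASP2 (−1.23 ± 0.154), LNK2 (1.12 ± 0.112), SVP (0.49 ± 0.0786) and PCS1 (0.62 ± 0.0945), with adjusted p of 0.00933 or lower. For abscisic acid and osmotic markers, 4 of 17 had a more positive and 1 a more negative response (6 and 4 adjusted over the list alone, adjusted p = 0.273, and 0.0246 without Col-0 control suffix 1). Of the SR factors 0 of 20 passed by limma, RS31 being at 0.36 ± 0.109 (adjusted p = 0.0670). Of the senescence genes it was 0 of 6, SAG29 being at 0.75 ± 0.291 (adjusted p = 0.133). Of the 2016 genes whose response differed, 1251 had a more positive and 765 a more negative response in smeb. Of these, 724 had fallen with salt in Col-0 with a more positive response in smeb. Another 510 had risen in Col-0 with a more negative response in smeb, and 323 had risen with a more positive one. The others were 123 that had fallen with a more negative response and 204 and 132 that were not called with salt in Col-0. The Col-0 response enters the difference with a minus sign from the same libraries, so part of the excess of opposite directions is built in.

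The count of 2016 was 1086 and 815 without Col-0 control suffix 0 or 1, 1264 without smeb-2 control suffix 1, and 5006 without Col-0 salt suffix 0, where 46.9% in place of 62.1% were more positive and 6 of the 9 list calls (all but photosynthesis, jasmonate and cell cycle) were lost at adjusted p between 0.0573 and 0.349, and heat shock (0.132 without Col-0 control suffix 0), salicylate (0.0757 without Col-0 control suffix 1) and the RCD1 family (between 0.0562 and 0.151 without any of the 4 Col-0 libraries) were lost elsewhere as well. Without at least one Col-0 control library the calls of AT4G30097, PYR1, NHX1, SRO4, CBF2, CBF1, SARD1, EDS1 and HSP90.1 were lost (adjusted p between 0.0505 and 0.117), and with a pseudocount of 0.1 those of AT2G17850 (0.0665), SRO4 (0.0845) and NDB4 (0.787, a difference of 0.185), and without single other libraries those of NHX1, CBF1, EDS1 and SRO4 (0.0507 to 0.0646), whereas RS31, SAG29 and CDKB2;1 passed without 1 Col-0 salt library (0.00957, 0.00227 and 0.00548), RS31 under median-of-ratios scaling (0.0468) and quantile normalization (0.0386), and CDKB2;1 with the column suffix as a block (0.0419).

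The design has both alleles so that effects of SmEb can be told from those of a single line. smeb-1 and smeb-2 differed from each other in 21 genes without salt (11 higher and 10 lower in smeb-2) and 58 in salt (36 and 22). SmEb was 26.8 ± 1.09 FPKM in smeb-1 and 5.58 ± 0.930 in smeb-2 without salt. Against Col-0 without salt, 4009 genes differed in smeb-1 (1845 higher, 2164 lower) and 3741 in smeb-2 (1736 higher, 2005 lower), with 1294 higher and 1581 lower in both and 1 opposite. In salt, 5587 differed in smeb-1 (2520 higher, 3067 lower) and 2783 in smeb-2 (1552 higher, 1231 lower), with 1298 higher and 1015 lower in both and 1 opposite. The salt response differed from Col-0 in 1726 genes for smeb-1 (1027 more positive, 699 more negative) and 1186 for smeb-2 (857 and 329), with 598 and 231 shared and 0 opposite by limma. The abscisic acid and osmotic list had 1 higher and 10 lower of 17 (1 and 12 adjusted over the list alone) in smeb-1 and 0 higher and 13 lower of 17 in smeb-2 without salt. In salt it had 0 higher and 13 lower of 17 (0 and 14 adjusted over the list alone) in smeb-1. In smeb-2, the line with less SmEb transcript, it had 0 higher and 3 lower of 17 (0 and 9 adjusted over the list alone).

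Both contrasts use the same Col-0 libraries, so some overlap arises with no effect at all. Independent lists of these sizes would share 158 higher and 214 lower in control, 193 and 186 in salt, and 43.5 and 11.4 for the salt response. Across genes, which are not independent replicates, the alleles' differences from Col-0 correlated at r = 0.888 in control (mean of 50 simulations of unchanged groups 0.501), 0.820 in salt (0.504) and 0.789 for the salt response (0.501). The covariance exceeded the simulated one by 0.121 (0.133 against 0.0118), 0.0942 (0.106 against 0.0118) and 0.118 (0.142 against 0.0235). The simulations gave all libraries the same spread for a gene, but the shared Col-0 salt pair varied more than the other groups. The simulated correlations and covariances are therefore too low in salt and for the salt response, and the excess over them there is overstated. The 2 control libraries cannot be split further, so part of the excess overlap of genes could come from the shared controls. The counts depended on which libraries were fitted. The spread is shared over groups and the Col-0 salt pair varied most, so counts against Col-0 in salt are likely too high. With only the groups compared, 197 genes differed in salt for smeb-1, 10 for smeb-2, and the salt response differed in 834 and 786. Leaving out single libraries moved the allele difference between 5 (without smeb-1 control suffix 1) and 59 (without Col-0 salt suffix 0) genes in control. In salt it lay between 4 (without smeb-1 salt suffix 0) and 610 (without Col-0 salt suffix 1).

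The authors also deposited lists of splicing events, 137 in 131 genes called SmEb-dependent and 208 in 199 genes called SmEb-independent, with no gene or event in both. In the authors' deposited table of dependent events, cassette exons made up 64 events, intron retention 27, alternative 3′ splice sites 17, alternative 5′ splice sites 15, multiple cassettes 8, alternative starts 5 and an alternative end 1. The share of reads not counted as skipping was lower in the salt-treated smeb column than in the Col-0 column for 58 of the 64 cassette events in the authors' deposited table, and higher for 6. For intron retention that share was higher in 23 and lower in 4, although the authors' deposited table does not say which form its read classes stand for there. The authors' deposited table of independent events, which compares salt-treated with untreated wild type, held 62 cassettes (24 higher and 38 lower) and 52 alternative 3′ splice sites (20 and 32). It also held 49 intron retentions (20 and 28) and 25 alternative 5′ splice sites (15 and 10). Cassettes were 46.7% of dependent and 29.8% of independent events in the authors' deposited tables (Fisher's exact test, two-sided, adjusted p = 0.0079 over 4 types), and alternative 3′ splice sites 12.4% and 25% (adjusted p = 0.00793). Intron retention (adjusted p = 0.571) and alternative 5′ splice sites (0.864) did not differ in share by that test on the authors' deposited tables. On the reference annotation, 45 of the 64 dependent and 38 of the 62 independent cassettes in the authors' deposited tables equalled an annotated exon. Likewise 23 of 27 and 28 of 49 intron retentions equalled an annotated intron within 1 base, and 4 and 19 lay inside an annotated exon.

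RCD1 was among the dependent cassettes in the authors' deposited table. Its event lay at chromosome 1, 11614983 to 11615161 in TAIR10, 179 bp inside annotated intron 4 (11614907 to 11615231), between the exons at 11614659 to 11614906 and 11615232 to 11615311. Reads not counted as skipping this segment were 2.1% (95% Wilson interval 1.2% to 3.63%, 572 reads) in the smeb column and 4.84% (3.69% to 6.32%, 1033 reads) in the Col-0 column of the authors' deposited table, whose FDR was 0.0302. FSD2, an iron superoxide dismutase of plastids, had an event at chromosome 5, 20775167 to 20775244, a 78 bp annotated exon. The share was 97.2% (95.7% to 98.2%, 719 reads) in smeb and 100% (99.4% to 100%, 666 reads) in Col-0 in the authors' deposited table (FDR = 0.0376). The SR factor RS40 had one at chromosome 4, 13024765 to 13024831, a 67 bp annotated exon. The share was 3.56% (1.94% to 6.43%, 281 reads) and 13.8% (10.8% to 17.42%, 414 reads) in the authors' deposited table (FDR = 0.00339). Among independent events in the authors' deposited table, the RCD1 relative SRO1 had a 103 bp cassette (chromosome 2, 14919733 to 14919835). The share was 94.2% (92.2% to 95.7%, 673 reads) and 99.8% (99.0% to 100%, 587 reads) in the authors' deposited table, FDR = 0.00175. The authors' deposited tables also list an alternative 5′ splice site in GR1 (96.7% of 1304 reads and 90% of 190 reads) and intron retention in the dehydrin ERD14 and in RBCS1A, a near-identical copy in its family. The ERD14 and RBCS1A segments lie inside an annotated exon and match no annotated exon boundary. Their shares in salt-treated and untreated wild type were 99.7% and 100% for ERD14 and 99.998% and 99.992% for RBCS1A in the authors' deposited table. Intervals cover counting error only, and the reads pool replicates. The authors' deposited tables hold only events that passed their selection, with no statement of which allele or treatment some columns hold.

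**Figure D3:**
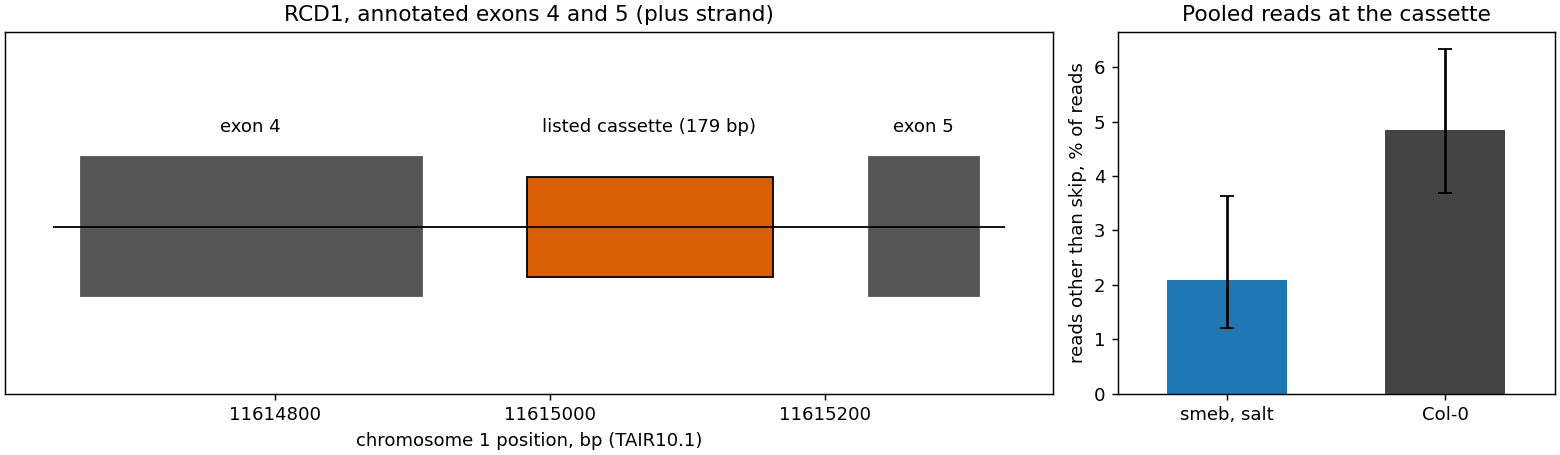
Left, map of the RCD1 segment on chromosome 1 (TAIR10, bp) with the flanking annotated exons 4 and 5 and the 179 bp cassette; right, percent of reads not counted as skipping it, with 95% Wilson intervals, in the authors' deposited table. The share was 2.1% in the smeb column and 4.84% in the Col-0 column.

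Gene-level expression of these lists was set beside the splicing events, although the authors chose the lists on these samples, so they are not independent evidence. In Col-0, 83 of 131 measured genes of the dependent list changed with salt (24 higher, 59 lower), 63.4% against 61.8% of all genes tested. In the independent list 125 of 195 did (53 higher, 72 lower, 64.1%). In smeb-1 the counts were 88 (31 and 57, 67.2%) and 122 (43 and 79, 62.6%) against 57.8% of all genes, and in smeb-2 83 (27 and 56, 63.4%) and 135 (53 and 82, 69.2%) against 59.7%. Between smeb and Col-0 in control 44 dependent genes (33.6%) and 63 independent ones (32.3%) differed against 24.5% of all genes, and in salt 40 (30.5%) and 70 (35.9%) against 27.7%. These shares are no test of enrichment, since the expression of the listed genes was not matched to that of all genes. By camera the independent list was lower in salt-treated smeb (adjusted p = 0.00815, and adjusted p = 0.629 with an estimated correlation). The other 3 of these tests did not pass (adjusted p between 0.0672 and 0.734). The salt response differed between smeb and Col-0 in 11 dependent genes (9 more positive, 2 more negative, and 6 genes adjusted over the list alone) and in 19 independent genes (11 and 8). These were 8.40% and 9.74% of the lists, against 9.96% of all genes. Among the first were the aldehyde dehydrogenase ALDH11A3 (0.81), AT5G25440 (1.25) and the photosystem II subunit PSBO1 (0.56), and among the second the hydrolase NUDT7 (1.26), HOL2 (−1.30) and GR1 (−0.52), picked here after their values were seen. By camera both lists were lower with salt in Col-0 (dependent adjusted p = 0.00186, independent 0.0412), in smeb-1 (0.00540 and 0.00540) and in smeb-2 (0.00641 and 0.0160). With an estimated correlation neither passed in Col-0 (adjusted p = 0.0732 and 0.465), smeb-1 (0.110 and 0.329) or smeb-2 (0.109 and 0.393), and neither list passed for the salt response (adjusted p = 0.174 and 0.283). The counts for the salt response rested on single libraries. There were 4 dependent genes without Col-0 control suffix 1 and 34 without Col-0 salt suffix 0. There were 5 independent genes without Col-0 control suffix 0 and 63 without Col-0 salt suffix 0.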

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

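The tests of root markers below were chosen only after the result was seen. Differences in salt response between smeb and Col-0, by the interaction term of limma, passed for 2016 genes with both alleles together, 1726 for smeb-1 and 1186 for smeb-2. By camera, 9 lists passed, with median log2 differences of 0.82 (photosynthesis), 0.83 (jasmonate), 0.47 (mitochondrial retrograde genes), 0.44 (CBF and DREB), 0.37 (salicylate), 0.28 (cell cycle), −0.16 (ion transport), −0.26 (RCD1 family) and −0.40 (heat shock). With an estimated correlation only photosynthesis passed (adjusted p = 0.0255), and the other 8 did not (0.172 for jasmonate and between 0.388 and 0.559 for the rest). Named genes with a more positive response in smeb were PS2 3.58, PEPC1 3.34, RD20 2.77, NPC4 2.68, LHCB2.1 2.43, AT12CYS 2.33, AOC1 2.15, LHCB3 2.02, LHCB4.2 1.84, HAI1 1.64, CBF2 1.60, P5CS1 1.51, HSP18.2 1.43, OPR3 1.23, LNK2 1.12, CAT2 1.05, NDB4 1.05, AOX1A 1.01, MYC2 1.003, SARD1 0.996, CYP707A2 0.90, CBF1 0.73, PCS1 0.62, SVP 0.49, EDS1 0.47. NDB4 fell to 0.185 with a pseudocount of 0.1 and no longer passed (adjusted p = 0.787). Named genes with a more negative response were AT4G39675 −3.90, ADH1 −3.60, TH8 −3.03, AT2G17850 −2.98, AT4G33070 −2.80, SRO5 −1.66, CASP2 −1.23, CAX1 −1.19, SmEb −1.06, AHA2 −0.72, HSP70 −0.72, HSP90.1 −0.67, PYR1 −0.60, NHX1 −0.43. The fitted differences of U1.5 (4.25), AT4G30097 (−6.06) and SRO4 (−1.31), which have groups listed at 0, depend on the pseudocount and are no bound.

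Photosynthesis genes fell further under salt in Col-0 than in both smeb alleles, by a median of 0.816 over 22 genes. A single aberrant Col-0 salt library as the whole cause is argued against by the medians of 0.753 and 0.899 after leaving out either one, and the scaling of FPKM by medians of 0.714 and 0.841 under the other scalings. Less shoot tissue in the Col-0 salt libraries would have left root markers lower in salt-treated smeb. Their median there was 0.418 (bootstrap SE 0.342), within 2 SE of 0 with 8 called higher and 2 lower, so this explanation stays open and cannot be told apart from an effect of SmEb. A growth or harvest batch shared by both smeb lines but not by Col-0 was not tested and stays open.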

How the results depend on the processing

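The runs of the gene lists without single libraries were chosen after seeing the data; all other alternatives were planned. Of 288 results for named genes, 0 reversed in the runs of limma made for them, which left out the fit of only the groups compared and the minimum fold. Over the 5 other settings 1405 values kept their side of the threshold, 26 lost it and 9 gained it, touching 24 results. Over the 12 runs without a library 3268 kept it, 176 lost it and 12 gained it, touching 66. A minimum fold of 2 left 3159 of 12520, 2671 of 11708 and 3001 of 12085 genes for salt in Col-0, smeb-1 and smeb-2. It left 489 of 4969 and 327 of 5617 for smeb against Col-0 in control and salt, and 498 of 2016 for the salt response. It left 530 of 4009 and 477 of 3741 for smeb-1 and smeb-2 in control, 546 of 5587 and 224 of 2783 in salt, 538 of 1726 and 465 of 1186 for their salt responses, and 10 of 21 and 18 of 58 between alleles in control and salt. With only the groups compared, counts were 2091 in place of 5617 for smeb in salt, 197 in place of 5587 and 10 in place of 2783 for smeb-1 and smeb-2 in salt, and 834 in place of 1726 and 786 in place of 1186 for their salt responses. They rose to 6559 in place of 4969 for smeb in control, 4749 in place of 4009 and 4671 in place of 3741 for smeb-1 and smeb-2 in control, and 11892 in place of 11708 and 12752 in place of 12085 for salt in smeb-1 and smeb-2, and fell to 9753 in place of 12520 for salt in Col-0. These falls were in comparisons that use Col-0 salt, the pair that varied most, and the rises in comparisons that do not. The allele difference in control was 12 with no filter and 11 with the block, in place of 21. Lists passing were 11, 5, 4 and 9 by camera with the preset correlation, 0, 0, 1 and 1 with an estimated one and 20, 13, 13 and 4 by fry for salt in Col-0, smeb in control, smeb in salt and the salt response. Under quantile normalization 52.3% in place of 46.0% of smeb-1 calls and 51.6% in place of 46.4% of smeb-2 calls were higher in control, and 53.9% in place of 45.1% for smeb-1 in salt. Without Col-0 salt suffix 0, 43.9% in place of 55.8% were higher for smeb-2 in salt, and 46.0% in place of 59.5% more positive for the salt response of smeb-1 and 50.6% in place of 72.3% for that of smeb-2. Without smeb-2 salt suffix 0, 72.2% were higher for smeb-2 in salt. Of smeb-1 calls in salt 51.9% and 50.9% were higher without smeb-1 salt suffix 0 or 1. The causes of these shifts were not tested. Read depth is not given, which leaves the precision of low FPKM values unknown.

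Without single libraries, counts ranged from 10508 to 12511 for salt in Col-0, 9560 to 12815 in smeb-1 and 9915 to 13080 in smeb-2. They ranged from 2385 (without Col-0 control suffix 1) to 6535 (without Col-0 salt suffix 1) for smeb in control and from 2982 (without Col-0 salt suffix 1) to 7918 (without Col-0 salt suffix 0) in salt, and for the salt response from 815 (without Col-0 control suffix 1) to 5006 (without Col-0 salt suffix 0). For smeb-1 they were 1625 to 5582 in control, 2805 to 8002 in salt and 640 to 4709 for the salt response, and for smeb-2 1612 to 5293, 695 to 6162 and 455 to 3684, the highest salt and response values all being without Col-0 salt suffix 0. The alleles differed in 5 to 59 genes in control and 4 to 610 in salt. Without each of the 4 Col-0 libraries only, lists passing were 10 to 11 for salt in Col-0, 5 to 5 in control, 3 to 5 in salt and 3 to 8 for the salt response. The 5 in control were not always the same, since without Col-0 control suffix 0 flowering passed (adjusted p = 0.0411 in place of 0.0990) and heat shock did not. Members called of the authors' dependent list were 72 to 89, 71 to 91, 67 to 87 and 4 to 34 for salt in Col-0, smeb-1, smeb-2 and the response difference, and of the independent list 101 to 126, 102 to 136, 109 to 148 and 5 to 63.

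The column suffixes did not pair the libraries: over 15 pairs of groups the correlation of deviations ranged from −0.125 to 0.112 (median 0.00935), with 2 above 0.1. With the suffix as a replicate block, counts were 12431, 11607 and 11966 for salt in Col-0, smeb-1 and smeb-2, 4850 and 5468 for smeb in control and salt, 1940 for the salt response, and 11 and 65 between alleles.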

Other observations

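The lists of phosphate starvation and low oxygen genes and the test of separately grown batches were chosen only after the data were seen; the touch and wound and the clock lists were written before. Untreated smeb seedlings had lower transcript of phosphate starvation genes: 22 of 22 measured genes were lower (median log2 difference −2.2, including the genes that prompted the list). The 15 of them outside the genes named by rule in the comparisons were all lower (median −1.46, unadjusted camera p = 1.55e-18, and p = 0.00498 with an estimated correlation). Genes of one response tend to move together, so neither these 15 nor the 17 low oxygen genes below are an independent test of their lists. SPX1, a phosphate sensor, was at 147 ± 0.686 FPKM in Col-0 control, 27.2 ± 4.90 in smeb-1 and 23.5 ± 0.623 in smeb-2, and PHT1;4, a phosphate transporter, at 32.3 ± 3.23, 10.4 ± 1.05 and 9.13 ± 1.01. In salt 8 of 22 were lower (median −0.29). In Col-0 salt lowered 16 and raised 4, and the salt response was more positive in smeb for 20 (median 1.47) and for 14 of the 15 (p = 0.00584 with an estimated correlation). Low oxygen genes went the other way: 21 of 22 were higher in untreated smeb (median 1.86), and 16 of the 17 outside the genes named by rule were (median 1.66, p = 0.0449 with an estimated correlation). HB1, a non-symbiotic hemoglobin, was at 11.5 ± 1.14 FPKM in Col-0 control, 75.2 ± 17.8 in smeb-1 and 57.1 ± 25.8 in smeb-2. In salt 4 were higher and 3 lower (median 0.12), and their salt response was more negative in smeb for 19 (median −1.45) and for 14 of the 17 (p = 0.0696 with an estimated correlation, which did not pass). By limma 0 genes of either list differed between the alleles in control over all genes, although low oxygen genes had a median of −0.257 in smeb-2 against smeb-1, and the 17 of them one of −0.248 (unadjusted camera p = 0.00182, and p = 0.343 with an estimated correlation). In that comparison 1365 of 20251 genes had an unadjusted p under 0.05.

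Gene families grouped by product name, 26 of them, were tested by camera as a description. Of 311 ribosomal protein genes 115 were higher and 2 lower in untreated smeb (median 0.16, adjusted p = 8.76e-15, and adjusted p = 0.330 with an estimated correlation), and of 41 extensin genes, which encode cell wall proteins, 18 were higher and 0 lower by limma. In salt 26 extensin genes were higher and 2 lower in smeb (median 0.51, adjusted p = 2.99e-08, and adjusted p = 0.427 with an estimated correlation). Of 62 SAUR genes, induced by auxin, 14 had a more positive and 2 a more negative salt response in smeb (median 0.40, adjusted p = 0.0400 with an estimated correlation). In smeb 5 were higher and 24 lower without salt (median −0.257), and 9 higher and 7 lower in salt (median −0.0015). Their difference in response thus went with the control difference, for which genotype and batch cannot be told apart. Of 118 heat shock protein genes 4 had a more positive and 14 a more negative response (median −0.14, adjusted p = 0.0400 with an estimated correlation). With salt in Col-0, 33 of 57 NAC genes rose and 6 fell, 25 of 46 WRKY genes rose and 3 fell, and 64 of 107 glycosyltransferase genes rose and 17 fell, none of these families passing with an estimated correlation (adjusted p = 0.461, 0.417 and 0.297).

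Abscisic acid, PP2C and jasmonate genes were lower in untreated smeb than in untreated Col-0, with a median of −0.754 over the 3 lists. A single aberrant Col-0 control library is argued against as the whole cause by medians of −0.684 and −0.713 without either one. The alleles differed in 21 genes, 0.561% of the 3741 that separate smeb-2 from Col-0. This argues against chance differences of like size between batches grown for each line separately. It cannot speak to a Col-0 batch that alone deviated, since both alleles would then differ from it alike. Touch or wounding of the Col-0 control seedlings stays open, since the touch and wound list had a median of −0.171 with 4 of 14 measured genes lower, between the bounds set for and against it. Called lower were LOX3 (−1.28), WRKY53 (−1.24), WRKY40 (−1.1) and LOX4 (−0.64), and called higher, opposite to that explanation, TCH4 (1.055) and TCH2 (0.52). A difference in growth conditions shared by both smeb lines may equally be the source, since phosphate starvation, low oxygen and clock genes differed in the same comparison, and genotype and such a batch cannot be told apart here.

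Salt changed clock genes in each genotype, and the harvest time of the controls is uncertain. Morning genes had median salt responses of −0.94 in Col-0, −0.14 in smeb-1 and −0.05 in smeb-2, and evening genes −1.07, −0.85 and −0.86. The test of another time of day at harvest asked whether morning and evening medians moved apart. They differed by 0.126 in Col-0, 0.709 in smeb-1 and 0.806 in smeb-2, which met neither bound in every genotype. Within the lists genes went both ways. In Col-0 the morning genes LHY (1.24) and RVE8 (1.38) rose, while LNK2 (−3.28), LNK1 (−2.22), PRR9 (−1.55) and CCA1 (−0.34) fell. Evening genes had 1 higher and 3 lower of 5. Opposite moves cancel in such medians, so the test cannot decide. This explanation cannot be told apart from an effect of salt on the clock. Without salt, 6 of 6 morning genes were lower in smeb (median −0.96, unadjusted p = 0.00281 with an estimated correlation) and 3 of 5 evening genes higher (median 0.42, p = 0.124), and the salt response of 5 morning genes was more positive in smeb (median 0.85, p = 0.00419) and that of 3 of 5 evening genes more negative (median −0.59, p = 0.105).

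4 genes were at 50 FPKM or more in 1 library and under 0.1 in all others: the metallothionein MT1A at 79.2 in smeb-1 salt suffix 0, AT2G11271 at 282 in Col-0 salt suffix 1, AT4G39366 at 519 in Col-0 salt suffix 0 and AT5G14560 at 277 in Col-0 control suffix 1. In the authors' deposited table of enriched terms for dependent events, mRNA processing led (9 of 122 genes, adjusted p = 0.0274), and response to oxygen radical (2 of 122) has p = 0.0017 with an adjusted p of 0.01, smaller than the adjusted p of 4 terms with smaller p, which a Benjamini-Hochberg adjustment over the same terms does not give. For independent events the authors' deposited table lists 9 terms, the first being starch biosynthesis (4 of 187 genes, adjusted p = 0.167).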
